A study of Drosophila melanogaster with 14 samples.

How the data were processed

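Nuclei of mushroom body neurons were profiled by RNA sequencing in male Drosophila melanogaster. Per the labels' protocols, the MB010B driver placed the tag unc84-GFP on the nuclei, nuclei were collected by immunoprecipitation of GFP (the INTACT method), and RNA was extracted with Trizol. Each replicate held about 20000 flies of 2 to 7 days raised at 25 C. Flies received 3 exposures and were killed 24 h after the last. The Air group received air and the EtOH group ethanol, both with 60 min between exposures. The Odors group received ethyl acetate and isoamyl alcohol for 10 min each, with 50 min between exposures. The Trained group received the same odors with ethanol on one of them. In Odors and in Trained, replicates 1 and 2 had ethyl acetate first and replicates 3 and 4 had isoamyl alcohol first.

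The authors trimmed reads with Trimmomatic 0.36, aligned them with HISAT2 2.0.5 to build BDGP6, handled alignments with SAMtools 1.3.1 and quantified transcripts with StringTie 1.3.3, per the submitters' processing notes. The deposited matrix holds estimated counts, also called expected counts, for 34741 transcripts in 14 columns, and every value was whole. No scaling or filter of the authors is recorded in the notes. Transcripts were paired with genes through their FlyBase identifiers in the reference annotation, Ensembl release 115 of assembly BDGP6.54, from which all coordinates printed are taken. This pairing covered 34262 transcripts of 17588 genes. The other 479 held 4.12 to 8.26% of the counts of a library, of which an identifier made of zeros held 2.64 to 4.36%, and they were left out of all tests.

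The columns Air 3 and EtOH 3 were not used in the comparisons. Their median rank correlations with the other 12 columns were 0.0922 and 0.0925, against 0.802 with each other. In 16 of 18 blocks of 2000 lines, their values matched the other columns better at neighbouring lines, up to 17 lines away, so the transcripts that these values belong to are uncertain. The design chosen before the data were examined had all 14 libraries in the fit. The comparisons therefore rest on 2 Air, 2 EtOH, 4 Odors and 4 Trained libraries, with total counts of 14149006 to 21702932.

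Counts were summed per gene. Features with enough counts in the smallest group (edgeR's filterByExpr, minimum count 10) were kept, which left 12382 genes and 21473 transcripts. Counts were scaled with TMM factors, and levels are given as CPM, counts scaled to a common library size with these factors. Groups were compared with edgeR 4.0.16 quasi-likelihood F tests in a single fit with all 12 libraries, so that they shared one estimate of the spread. The threshold was a Benjamini-Hochberg adjusted p of 0.05. All p-values are two-sided, and adjusted p-values of genes and transcripts come from edgeR unless another tool is named. Changes are log2 fold changes with their standard error (SE). Transcript usage, the share of a gene's counts in each of its kept transcripts, was tested with edgeR's diffSpliceDGE and Simes adjustment in 4642 genes. Shares printed for genes with a usage call are of the kept transcripts unless stated. The biological coefficient of variation was 0.562 for genes and 1.31 for transcripts.

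The 33 gene lists, 9 of them cell type markers, were written before the data were examined, and 954 of their entries matched an annotated gene. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Calculations ran in R 4.3.3 with DESeq2 1.42.0 as the alternative tool, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The p-values measure the spread between these libraries, which may be technical in part. A fold against a group with every library at 0 is given as a lower bound, with a floor of 3 counts per library. Such floors cover counting error alone.

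The groups, comparisons, tests, alternatives and the rule for naming genes were chosen before the data were examined. Per comparison, the rule names up to 10 genes per direction with the smallest p among those past the threshold, or the 5 genes with the smallest p where fewer than 5 passed. It names up to 6 transcripts per direction, or the 3 with the smallest p where fewer than 3 passed, and the 6 genes with the smallest p for usage. It also names, from each list described, up to 4 members past the threshold, or otherwise the 2 with the smallest p, and in every case Dop2R, Stat92E, N and sca. Where these were many, the text gives some and summarises the others.

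Each test was first checked on simulated counts drawn from the means and library sizes of these libraries, with 200 features changed per fit. For Trained against Odors, 53% of genes changed 2-fold and 73% of those changed 4-fold were recovered, with 10 unchanged genes called among 11881. For EtOH against Air these shares were 11% and 56%, and for Odors against Air 27% and 64%. Among transcripts, 2% of those changed 4-fold and 44% of those changed 64-fold were recovered for Trained against Odors, 0% and 36% for EtOH against Air, and 2% and 46% for Odors against Air. Simulated usage changes of 4-fold and 64-fold were recovered in 0% of genes at the fitted spread. There 3 unchanged genes were called for Odors against Air, and 0 for Trained against Odors and for EtOH against Air. At the spread of these libraries the check therefore gives no support to usage calls. To check the code alone, a dispersion of 0.1 was also used, far below the fitted spread of transcripts. With it, 86% and 96% were recovered for Trained against Odors, with 26 unchanged genes called among 4445. For EtOH against Air these were 46% and 95%, with 17 unchanged genes called, and for Odors against Air 57% and 97%, with 16. A list shifted 1.5-fold was recovered in each of these 3 comparisons.

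Alternatives were the RLE scaling, no low-count filter, DESeq2's Wald test or limma's diffSplice, a fit of the compared groups alone, a replicate block, a term for odor order, both together, and each library left out in turn. Alternatives chosen after seeing the data were all 14 columns, a covariate for muscle or fat body markers, Odors 1 and 3 left out together, and robust empirical Bayes moderation.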

Results

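RNA from immunopurified mushroom body nuclei was sequenced 24 h after flies were exposed to air, ethanol, a pair of odors, or the odors with ethanol on one of them. The 12 libraries compared comprised 2 of Air, 2 of EtOH, 4 of Odors and 4 of Trained flies. Total estimated counts ranged from 14149006 in EtOH 1 to 21702932 in Odors 3. Markers of Kenyon cells, the intrinsic neurons of the mushroom body, summed to 18529 ± 1344 CPM in Trained and 17208 ± 2339 CPM in Odors (SD, n = 4 each). Their sums were 13980 and 18461 CPM in Air 1 and Air 2, and 12251 and 17726 in EtOH 1 and EtOH 2. Photoreceptor markers summed to 9627 ± 1971 CPM in Trained and 11491 ± 2291 in Odors (SD, n = 4 each). The libraries therefore cannot be taken as RNA of Kenyon cells alone. Air 1 and EtOH 1 lay apart from the other libraries on the first principal component, which held 42.6% of the variance, with scores of -114 and -141. On the second component (12.9%) Air 2 lay apart, at -111 against -23.8 to 22.5 in the others, and it had the fewest detected genes (10396) and transcripts (14789). In EtOH 1, ribosomal RNA held 8.43% of the counts and pseudogenes 5.59%, against at most 2.51% and 1.18% in the other 11 libraries.

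Trained and Odors flies differed in the ethanol paired with an odor, so this comparison asked which nuclear transcripts accompany the pairing. Stat92E (FBgn0016917, BDGP6.54 chromosome 3R, 20535323 to 20552311), the transcription factor of the JAK-STAT pathway, averaged 255 ± 17.99 CPM in Trained and 169 ± 11.4 in Odors (SD, n = 4 each). Its log2 change was 0.59 (SE 0.0864), with all Trained libraries above all Odors libraries. The adjusted p was 0.288 over all genes, and Stat92E passed when adjusted over the JAK-STAT list alone. The phosphoserine phosphatase gene aay (FBgn0023129, 3L, 9423253 to 9424781) averaged 92.2 ± 16.3 against 44.0 ± 8.10 CPM, a log2 change of 1.07 (SE 0.164, adjusted p 0.288). Nmdmc (FBgn0010222, 3R, 9042508 to 9050555), which encodes a mitochondrial folate dehydrogenase, averaged 56.6 ± 9.78 against 18.9 ± 7.13 CPM (log2 1.58, SE 0.265, adjusted p 0.356). CG5958 differed by log2 1.13 (SE 0.211, adjusted p 0.604). The cytochrome P450 gene Cyp4e3 (FBgn0015035, 2L, 9747839 to 9750071) was lower in Trained, at 6.86 ± 1.72 against 28.3 ± 13.2 CPM (log2 -2.04, SE 0.348, adjusted p 0.356), and passed when adjusted over the detoxification list alone. These 5 genes had the smallest p of the comparison, and none passed over all genes. In the 4 Air and EtOH libraries, aay lay at 61.5 to 97.9 CPM, Nmdmc at 32.8 to 68.5 and CG5958 at 18.6 to 24.5. These levels overlapped those of Trained (69.4 to 105, 47.9 to 65.3 and 17.7 to 23.0 CPM), and Odors lay below them (36.3 to 52.7, 11.9 to 25.2 and 6.37 to 11.1 CPM). Cyp4e3 lay at 8.38 to 13.8 CPM in Air and EtOH, which overlapped both Trained (5.70 to 9.42) and Odors (13.2 to 45.3). Stat92E lay at 164 to 188 CPM in Air and EtOH, near Odors. Among the genes named in advance, sca (log2 0.077, SE 0.110), N (-0.26, SE 0.408) and the dopamine receptor gene Dop2R (0.14, SE 0.158) had adjusted p of 1. With edgeR 0 of 12382 genes passed, 221 had an unadjusted p under 0.05, and DESeq2 called 12.

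**Figure D1:**
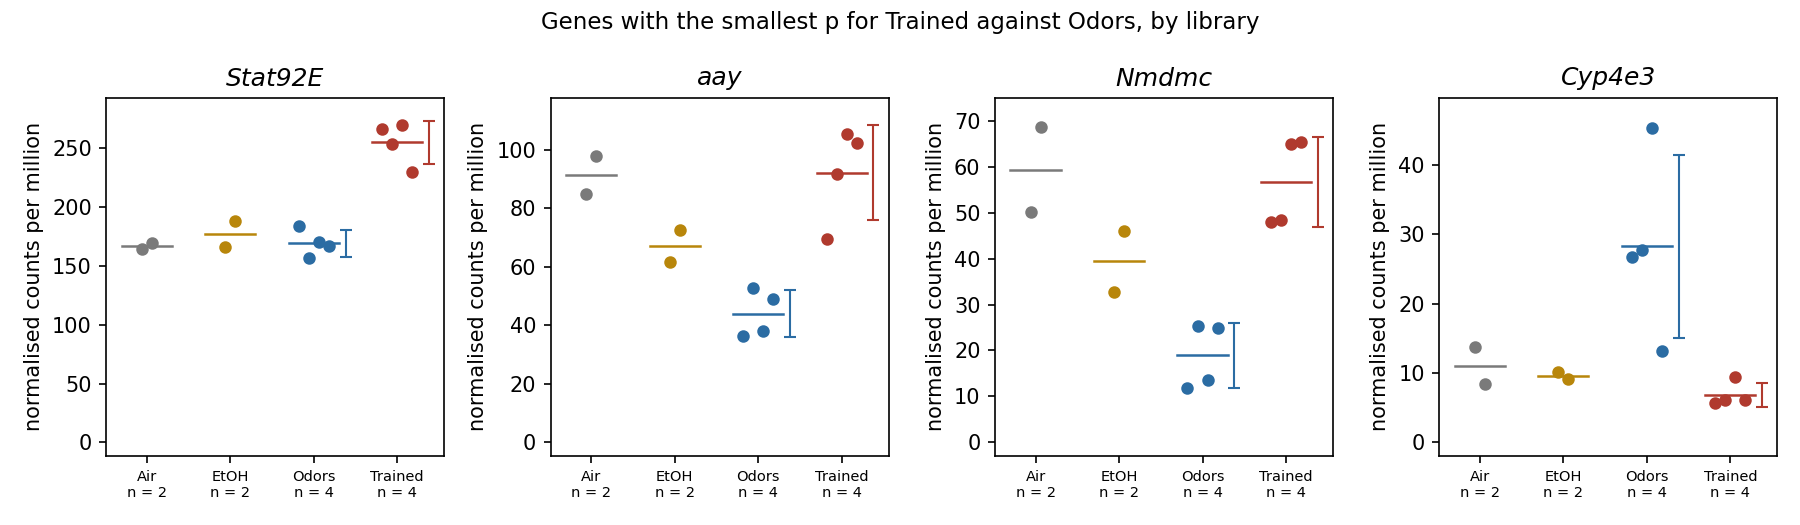
Normalised CPM (y axis) of Stat92E, aay, Nmdmc and Cyp4e3 in each library (points) by group (x axis), with group means as lines and SD bars for groups of 4. Stat92E lay at 230 to 270 CPM in the Trained libraries and at 156 to 184 in the Odors libraries.

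At the level of single transcripts, Gyf-RF and Gyf-RD, from a gene of a GYF-domain protein on chromosome 4 (855400 to 867025), were at 0 in every Odors, Air and EtOH library. They averaged 66.2 ± 23.1 and 72.1 ± 31.0 CPM in Trained (SD, n = 4), at least 306-fold and 333-fold above the floor of Odors. The dynamin transcript shi-RP (gene at X, 15892200 to 15906716) was at 0 in every Trained library and at 33.3 ± 4.83 CPM in Odors (at least 150-fold). These 3 transcripts had the smallest p, with an adjusted p of 0.231, and with edgeR 0 of 21473 transcripts passed. An unadjusted p under 0.05 was found for 744 transcripts, and DESeq2 called 313. The edgeR count was 2, 1, 1 and 2 without Trained 1, 2, 3 and 4, and 2 and 3 without Odors 3 and 4.

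Transcript usage differed in 5 of 4642 genes with edgeR, and limma's diffSplice called 4. With the letter of the title as a block edgeR called 1, and 0 with a term for odor order, alone or with that block. Stat92E was among the 5 (adjusted p 0.0341). Of the counts in its kept transcripts, Stat92E-RH held 83.8 ± 13.7% in Trained and 0.0168 ± 0.0202% in Odors, while Stat92E-RI held 3.15 ± 2.15% and 96.3 ± 1.04% (SD, n = 4 each). Over all transcripts of the gene, Stat92E-RH held 65.9 to 99.1% in the Trained libraries. Among kept transcripts Stat92E-RI also led in Air 1, Air 2 and EtOH 2, with 96.0, 96.9 and 96.4%, but EtOH 1 had 87.9% of Stat92E-RH at a gene level of 166 CPM. The pair of transcripts shares 3229 of 3830 and 3879 exonic bases; Stat92E-RI has an internal exon of 263 bases (3R, 20538453 to 20538715) that Stat92E-RH lacks. The long non-coding RNA lncRNA:Hsromega (adjusted p 0.000554) rested on Trained 3, where Hsromega-RD held 92.4% of its counts, and without Trained 3 the adjusted p was 0.825. The others were 14-3-3zeta (0.00829), the cytoskeletal linker gene shot (0.0216) and CG7564 (0.0432). For 14-3-3zeta, the RG transcript held 5.21% in Odors 4 and 18.9% in Air 2, and at most 0.0152% in the other 10 libraries. The usage call of Stat92E was lost when any 1 Odors or Trained library other than Trained 1 was left out, with adjusted p up to 0.244 without Odors 3. The usage count was 3, 2, 1 and 2 without Trained 1, 2, 3 and 4, and 8, 2 and 3 without Odors 1, 3 and 4.

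**Figure D2:**
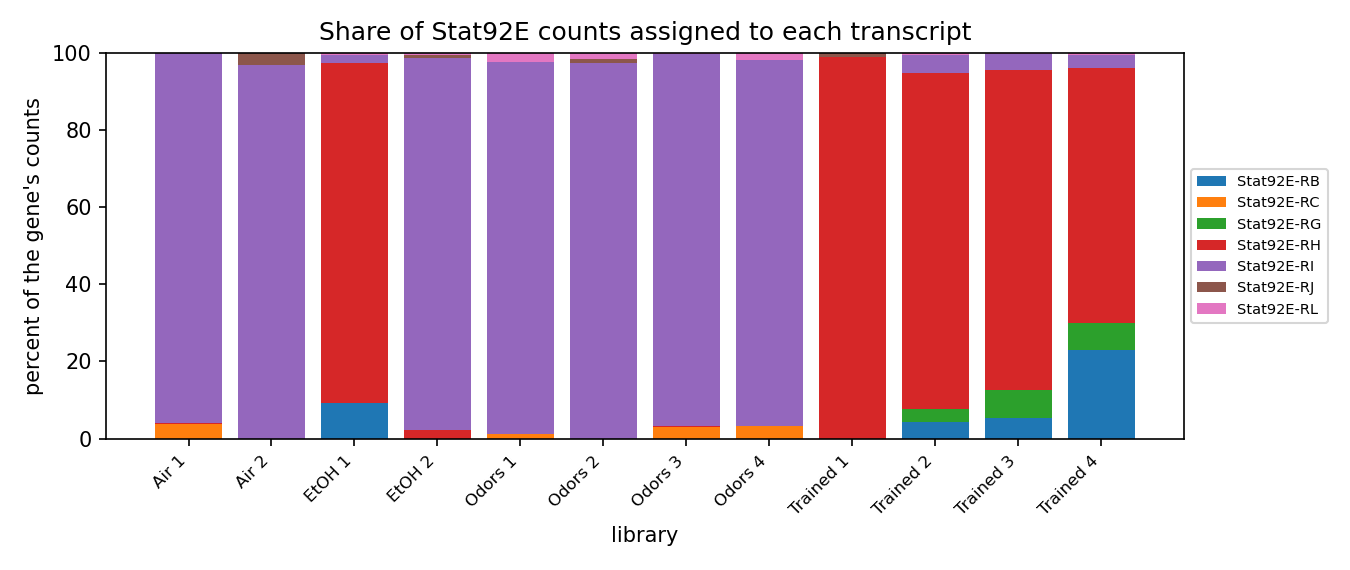
Stacked bars of the percent of Stat92E counts (y axis) assigned to each of its kept transcripts in each of the 12 libraries (x axis). Bar heights show shares and not the level of the gene. Stat92E-RH made up most of the gene in the 4 Trained libraries and in EtOH 1, and Stat92E-RI in the others.

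Among the lists, markers of fat body and hemolymph were higher in Trained than in Odors in 10 of 12 genes, with a median log2 change of 0.92 and 6 genes past when adjusted over the list alone. Their camera adjusted p was 5.25e-12, and 0.196 with an estimated correlation. Obp99b (log2 2.24, SE 0.548) and fit (3.27, SE 0.938) had the smallest p, and the sum over the list was 2371 ± 321 CPM in Trained and 1328 ± 366 in Odors (SD, n = 4 each). Cytosolic ribosomal protein genes were lower in 87 of 91 genes by a small median of -0.13 (camera adjusted p 2.15e-08, 0.621 with an estimated correlation). Heat shock and chaperone genes were lower in 15 of 21 (median -0.20, camera adjusted p 0.000157, 0.196 with an estimated correlation), led by Hsp68 (log2 -0.91, SE 0.262). Genes of transmitter-gated receptors were higher in 23 of 25 (median 0.16, camera adjusted p 2.54e-05, 0.621 with an estimated correlation). Muscle markers were lower in 16 of 16 (median -1.12, camera adjusted p 0.00367, 0.621 with an estimated correlation). They summed to 663 to 6176 CPM in the 6 libraries with the letter a in their title, and to 337 to 876 in the 6 with the letter b. The sums were 932, 876, 6176 and 441 CPM in Odors 1 to 4, and 663, 337, 2419 and 497 CPM in Trained 1 to 4, so Odors 3 carried most of the summed level of Odors. A further 4 lists passed at the preset correlation, of photoreceptors (median -0.23), ion channels (0.15), axon guidance (0.093) and synaptic vesicles (0.11), each with an adjusted p of 0.621 with an estimated correlation.

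**Figure D3:**
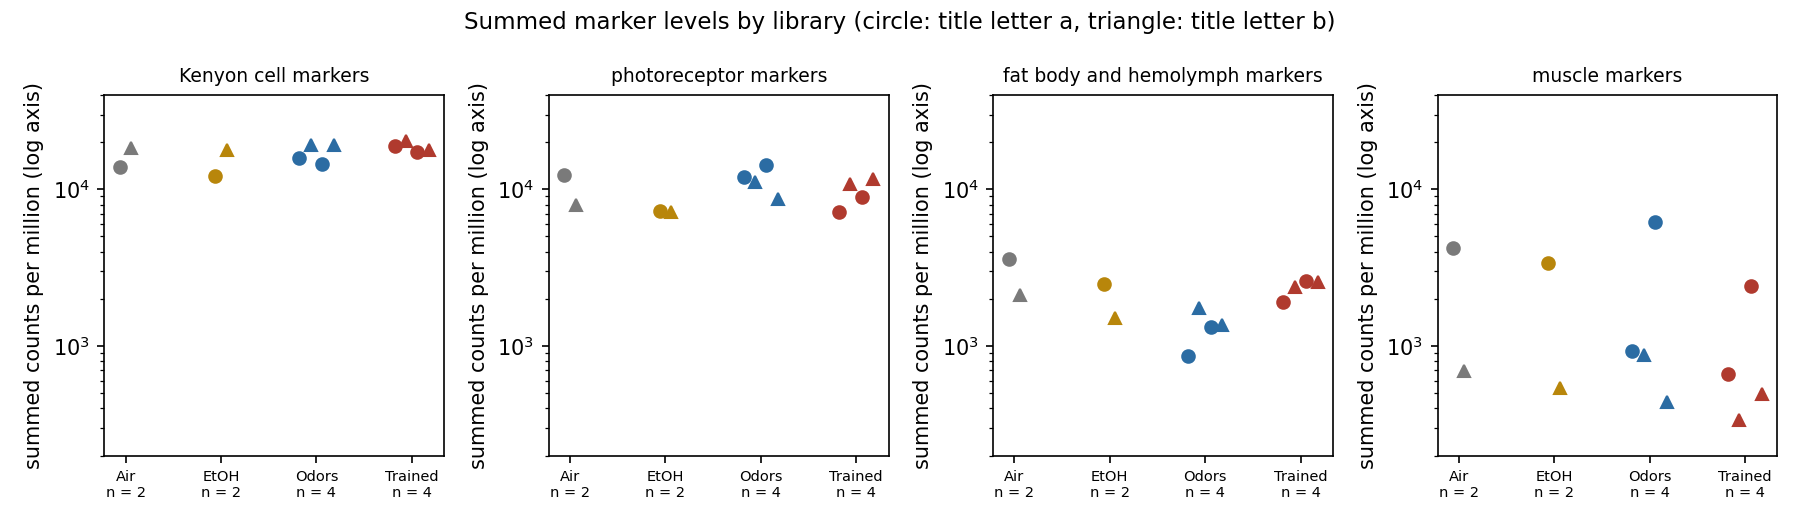
Summed normalised CPM (y axis, log scale) of the markers of Kenyon cells, photoreceptors, fat body and hemolymph, and muscle in each library, by group (x axis); circles have the letter a in their title and triangles the letter b. Fat body markers were higher in Trained than in Odors, and muscle markers reached 6176 CPM in Odors 3.

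EtOH and Air flies had the same schedule without odors, so this comparison asked for effects of ethanol alone. The lysosomal channel gene Trpml (3L, 19714418 to 19718328) and CG42638 (3L, 19745834 to 19749744) were at 0 in both Air libraries and at 45.1 ± 5.72 CPM in EtOH (SD, n = 2), at least 212-fold higher (adjusted p 1.15e-08). They had identical values in every library, so which of them gave the reads is uncertain. Shawn (FBgn0031039, X, 19611526 to 19615617), a mitochondrial carrier gene, was at 39.9 ± 3.83 CPM in EtOH and 0 in Air (at least 187-fold, adjusted p 1.67e-07). The receptor guanylate cyclase gene Gyc76C (3L, 19750943 to 19793569) was at least 61.4-fold higher (adjusted p 0.000117). Genes with counts in both groups that rose were trv (3R, 28026615 to 28090740, log2 3.28, SE 0.204, adjusted p 1.97e-05), the nuclear pore assembly gene Elys (X, 19652305 to 19659407, 2.96, SE 0.249, 0.000306) and Axud1 (1.56, SE 0.197, 0.00947). By these coordinates Trpml, CG42638 and Gyc76C lie close together on 3L, and Shawn and Elys on X. These calls may therefore not be independent of one another, which was not tested. The other 4 called genes, the water-sensing channel gene ppk28, Urm1, dyw and Rsph1, were at 0 in both Air libraries, with bounds of 18.4-fold to 25.8-fold. In all 11 of 12382 genes passed with edgeR, each higher in EtOH, 642 had an unadjusted p under 0.05, and DESeq2 called 94. The count was 271, 55, 40 and 37 without Air 1, Air 2, EtOH 1 and EtOH 2. A fit of the 4 Air and EtOH libraries alone called 0 genes. Grouping Air 1 with EtOH 1 against Air 2 with EtOH 2 gave 364 genes. Stat92E (log2 0.085, SE 0.122), sca (-0.23, SE 0.155), N (0.46, SE 0.577) and Dop2R (-0.14, SE 0.223) had adjusted p of 1.

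Of 97 transcripts past the threshold, 78 were higher in EtOH and 19 lower, with 69 at 0 in both Air libraries and 10 at 0 in both EtOH libraries. DESeq2 called 1689. Among the transcripts named for the smallest p, the largest bounds higher in EtOH were SP1173-RA (at least 989-fold), EMC1-RA (708-fold) and MESK2-RD (558-fold). The largest lower in EtOH were nonA-l-RA (348-fold) and lola-RI (316-fold). Other called transcripts with a larger p had bounds above that of SP1173-RA, such as CG9813-RC (5050-fold), CG9813-RD (2954-fold) and CG13917-RA (1916-fold). The bound of XNP-RA was 909-fold. lola-RI was at 22.03 CPM in Air 1 and 130 in Air 2, and its log2 change was -11.36 without Air 2 and -13.92 without Air 1. The count was 668, 312, 219 and 306 without Air 1, Air 2, EtOH 1 and EtOH 2. Usage differed in 39 genes with edgeR, and limma's diffSplice called 98. The chromatin remodeller gene XNP led (adjusted p 0.000177), with XNP-RA at 0 in both Air libraries, followed by eIF4A, Ugt316A1, the vesicle traffic gene Rab8, CG31191 and nonA-l (each 0.00251). The usage count was 14, 18 and 25 without Air 1, Air 2 and EtOH 1. Photoreceptor (median -0.45, camera adjusted p 0.0127) and glial markers (median -0.24, 0.0385) were lower in EtOH, each with an adjusted p of 0.915 with an estimated correlation. The photoreceptor sum was 12377 and 7952 CPM in Air 1 and Air 2, and 7283 and 7129 in EtOH 1 and EtOH 2. Air 1 thus carried most of that difference. Among Kenyon cell markers, Eip93F (log2 2.37, SE 0.580) passed when adjusted over the list alone.

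Odors against Air asked for the effect of the odors, though the spacing differed as well, at 50 against 60 min. Of 8967 transcripts with a median above 10 CPM, 488 to 926 were at 0 in the Air and EtOH libraries. In the Odors and Trained libraries 186 to 435 were. Other differences between these sets of libraries cannot be told apart from an effect of the odors. The RNA-binding protein gene stau (FBgn0003520, 2R, 18117896 to 18125779) rose from 42.3 and 39.3 CPM in Air to 194 ± 11.95 in Odors (SD, n = 4, log2 2.25, SE 0.127, adjusted p 6.06e-06). Its transcript stau-RA held 94.2 to 100% of the gene in Odors and Trained libraries and 6.14 to 61.0% in Air and EtOH libraries. trv (log2 3.60, SE 0.196, adjusted p 5.09e-06), Elys (2.78, SE 0.232, 0.000239) and Axud1 (1.70, SE 0.181, 0.00186) rose as well. The genes Trpml and CG42638, with their identical values (adjusted p 7.39e-09), Shawn (1.58e-07), Gyc76C (9.59e-05), ppk28 (0.000239) and Urm1 (0.000479) were again at 0 in Air, and these are the same Air libraries as above. Those that fell were the calcineurin gene Pp2B-14D (log2 -1.28, SE 0.193, adjusted p 0.0297), the chloride channel gene pHCl-1 (-1.70, SE 0.259, 0.0304), the pyrimidine catabolism gene su(r) (-1.42, SE 0.226, 0.0389) and the arginine kinase gene Argk1 (-3.25, SE 0.546, 0.0493). Argk1 was at 84.8 CPM in Air 1 and 667 in Air 2, and without Air 2 its log2 change was -1.10. The calls of Pp2B-14D, pHCl-1, su(r) and Argk1 were each lost without at least 1 library. With edgeR 25 genes passed, 21 higher and 4 lower, with 11 of them at 0 in both Air libraries, and DESeq2 called 262. The count was 507, 71, 15, 13 and 13 without Air 1, Air 2, Odors 1, Odors 2 and Odors 4. Stat92E (log2 0.021, SE 0.106, adjusted p 0.951), sca (0.070, SE 0.134, 0.867), N (0.10, SE 0.501, 0.951) and Dop2R (-0.11, SE 0.192, 0.854) did not pass.

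**Figure D4:**
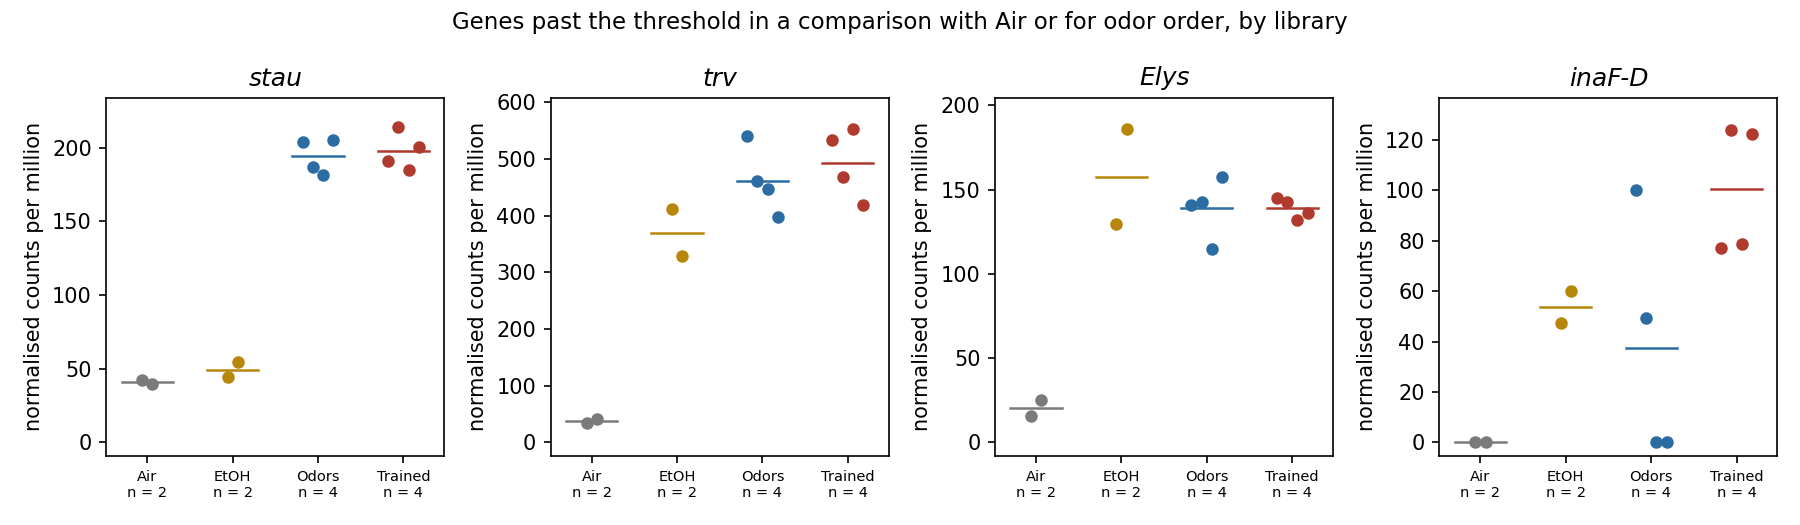
Normalised CPM (y axis) of stau, trv, Elys and inaF-D in each library (points) by group (x axis), with group means as lines. The levels of stau were 39.3 to 54.7 CPM in Air and EtOH and 181 to 214 in Odors and Trained.

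For the same comparison 123 transcripts passed, 103 higher and 20 lower, with 91 at 0 in every library of one group, and DESeq2 called 2225. Those that fell included Bx-RD (log2 -4.85, SE 0.341, adjusted p 9.89e-05) and CG11474-RC (-3.84, SE 0.459, 0.00475). The count was 795 and 352 without Air 1 and Air 2. Usage differed in 53 genes, and limma's diffSplice called 222. XNP (adjusted p 0.000131) was followed by Kap3 and alphaCOP (0.00063 each), eIF4A (0.000739), Aplip1 (0.000984) and Ugt316A1 (0.00107). In Kap3, a kinesin subunit gene, Kap3-RG held 91.4 ± 2.30% of the counts in Odors and 90.9 ± 3.59% in Trained (SD, n = 4 each) and 0 in Air and EtOH, where Kap3-RH held 32.0 to 100%. Fat body markers were lower in Odors than in Air in 9 of 12 genes (median -1.25, camera adjusted p 0.000952, 0.943 with an estimated correlation), 5 of them past when adjusted over the list alone. Lsp1beta (log2 -3.54, SE 0.862) and Obp99b (-2.53, SE 0.619) had the smallest p of that list. Past when adjusted over the list alone were also Sxl (log2 1.14), Eip93F (2.58), pen-2 (1.41) and Bx (0.84), each in a list of its own, and stau in the memory gene list.

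Trained against EtOH set ethanol with odors against ethanol alone, again with spacings of 50 and 60 min and with more transcripts at 0 in the EtOH libraries. stau rose (log2 2.00, SE 0.125, adjusted p 8.88e-05), and tyf (X, 4117020 to 4130016), whose product activates translation in the clock, fell (-2.52, SE 0.313, 0.0417). tyf-RN held 35.9 to 100% of that gene in Air and EtOH and at most 10.7% in Odors and Trained. The genes next in p were Sxl (log2 1.26, SE 0.198), CkIalpha (0.76, SE 0.119) and CRAT (1.26, SE 0.204), each with an adjusted p of 0.156, and Stat92E differed by 0.53 (SE 0.108, 0.170). These were 2 genes past the threshold with edgeR, against 214 with DESeq2 and 1505 at an unadjusted p under 0.05. The count was 23 and 57 without EtOH 1 and EtOH 2, and 1 without any one Trained library. Of 29 transcripts past the threshold, 26 were higher, among them Kap3-RG (at least 786-fold) and alphaCOP-RB (459-fold), and 24 were at 0 in every library of one group. The transcript count was 166 and 242 without EtOH 1 and EtOH 2, and DESeq2 called 1470. Of the lists, 10 passed with camera, led by synaptic vesicle genes (27 of 29 higher, median 0.41, camera adjusted p 3.18e-05, 0.480 with an estimated correlation) and transmitter-gated receptors (24 of 25 higher, median 0.36, 3.87e-05, 0.508 with an estimated correlation). The synaptic vesicle sum was 11030 CPM in EtOH 1, 15587 in EtOH 2 and 16342 to 18635 in Trained. The receptor sum was 4566, 6226 and 6530 to 7383 CPM, so both were lowest in EtOH 1.

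The interaction asked whether the change with ethanol differed with and without odors. It called 10 genes, all lower, which were CG42638, Trpml, Shawn, trv (log2 -3.19, SE 0.236, adjusted p 0.000123), Gyc76C, ppk28, Elys (-2.96, SE 0.291, 0.00126), Urm1, dyw and Rsph1. In 8 of them both Air libraries were at 0. All 10 were among the genes called for EtOH against Air, and Trained against Odors called 0, so the interaction largely repeats those calls. DESeq2 called 59, and edgeR called 251, 40 and 36 without Air 1, Air 2 and EtOH 1. Among transcripts 77 passed, 16 higher and 61 lower, against 1455 with DESeq2 and 618, 285, 198 and 246 without Air 1, Air 2, EtOH 1 and EtOH 2. Fat body markers were higher in 10 of 12 (median 1.13, camera adjusted p 0.000236, 0.726 with an estimated correlation). Across 12382 genes, which are not independent replicates, the log2 changes of Trained against Odors and of EtOH against Air had a Pearson r of -0.078 and a Spearman rho of -0.144. Without EtOH 1 the Pearson r was 0.182 and without Odors 3 it was 0.0282. From mean log CPM the r was -0.135, and an r as large in size came from 37 of 105 groupings of the libraries, so it did not exceed what regrouping gives.

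Reciprocal odor orders allowed a test of which odor came first. inaF-D (FBgn0260812, X, 11724668 to 11729099) is from a locus of photoreceptor channel partners. Averaged over Odors and Trained, it was higher with ethyl acetate first (log2 4.38, SE 0.350, adjusted p 0.0205). Its levels were 100.1 and 49.4 CPM in Odors 1 and 2, 0.184 and 0.134 in Odors 3 and 4, and 77.0 to 124 in the Trained libraries. The difference thus lay in Odors 3 and 4, and Trained showed no such drop with isoamyl alcohol first. RalGPS was next (log2 1.43, SE 0.164, adjusted p 0.0693) and did not pass, nor did Obp57b, promL and CG13954. With edgeR 1 gene passed, 189 had an unadjusted p under 0.05, and DESeq2 called 16. inaF-D was also the gene past the threshold for the difference between orders in the change with training (log2 -8.77, SE 0.700, adjusted p 0.0204), where DESeq2 called 14. This call of inaF-D rests on the same low values of Odors 3 and 4 and is not a separate finding. With the letter of the title as a block neither count held a gene, nor without Trained 2 or Odors 4. inaF-D itself also lost the first call without Trained 3 (adjusted p 0.107) and both without Odors 3 (0.156 and 0.234). Without Odors 1, Odors 2 and Trained 4 the first count was 3, 2 and 4 and the other 3, 5 and 5; the other was 2 without Trained 3 and 0 without Trained 1.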

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

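The tests with muscle or fat body markers as a covariate, of the Stat92E gene sum, of sequencing depth, of values at 0 shared by pairs of libraries, and of the calls kept with a block by the letter of the title were chosen only after the results were seen.

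Several values of single libraries lay far from the other 3 of their group, by the gap to the nearest relative to the whole range. Odors 3 had a total count of 21.7 M (21702932) and muscle markers of 6176 CPM, and Trained 3 had muscle markers of 2419 CPM. Trained 4 lay low in acetylcholine neuron markers (2128 CPM), sca (200.6 CPM) and Dop2R (309 CPM), and Trained 3 lay high in Cyp4e3 (9.42 CPM). The transcript Hsromega-RD of lncRNA:Hsromega held 92.4% of its gene in Trained 3 and 0.0431% in Odors 3, the highest of each group. The share of the RG transcript of 14-3-3zeta was 5.21% in Odors 4 and 0.00153% in Trained 3. Of 66 groups of values examined, 11 stood out in this way, where chance gives about 1 in 20 for independent values with a normal spread. The groups include CPM on a linear scale and transcript shares of genes picked for their usage calls. The number that stood out therefore cannot be read as an excess over chance.

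The interaction genes were all among the 11 called for EtOH against Air, and 8 of them were at 0 in both Air libraries. Trained against Odors called 0 genes, so these calls largely repeat those of EtOH against Air. By edgeR's test of the interaction, 10 genes passed, Trpml, CG42638, Shawn, trv, Gyc76C, ppk28, Elys, Urm1, dyw and Rsph1, and 77 transcripts. These counts were 251 and 618 without Air 1, 40 and 285 without Air 2, 36 and 198 without EtOH 1, and 15 and 246 without EtOH 2. The change with training differed between the odor orders in 1 gene, inaF-D, and in 0 without Trained 1, Trained 2 or Odors 4. The call of inaF-D rested on its low values in Odors 3 and 4. DESeq2 called 14 genes for the difference between the orders, and 88 had an unadjusted p under 0.05. It was 3, 5, 2 and 5 genes without Odors 1, Odors 2, Trained 3 and Trained 4.

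The columns Air 3 and EtOH 3, which no comparison used, had a rank correlation of 0.802 with each other and of about 0.0922 with the other 12 columns.

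Stat92E had a higher level and another main transcript in Trained than in Odors; the level is that of the gene sum (log2 difference 0.59, SE 0.0864), which is the pattern itself and tests no explanation of it. RNA of muscle as the source of the higher level is argued against, since the difference was 0.59 (SE 0.0887) with the muscle markers as a covariate. With the fat body markers it was 0.76 (SE 0.109), but these separate the Trained from the Odors libraries, so that covariate cannot decide. In Air and EtOH the fat body sum was 1504 to 3605 CPM, across the Trained range of 1911 to 2604. Stat92E lay at 164 to 188 CPM there, which argues against fat body RNA as the source of its level. The switch of transcript stays open. In 43.6% of 4043 genes the main transcript, the one with most of the gene's counts, was not the same in all Odors libraries. A library in which no transcript held most of the counts was counted as different, so outright switches may be fewer. EtOH 1 also carried Stat92E-RH without the higher level. A switch between all Trained and all Odors libraries was seen in 6 genes, against up to 8 in other splits of the same libraries (9 of the 35 splits gave as many), so chance cannot be excluded. A response of Stat92E to ethanol paired with an odor is a hypothesis for the level, which did not pass over all genes with edgeR, and effects of the treatment other than the pairing remain untested.

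Most calls against Air were of features at 0 in both Air libraries, among them the genes Trpml, CG42638 and Shawn. The smallest count expected in an Air library, from the level in the other 10, was 31.8 for the 8 such genes and 10.5 for the 69 such transcripts of EtOH against Air. For Odors against Air it was 20.1 for the 11 genes and 12.2 for the 90 transcripts. Passing the filter and the threshold favours features with high counts elsewhere, so small expected counts were unlikely and these values decide little about sequencing depth. For EtOH against Air the total counts argue against depth. They were 15.78 M and 15.26 M in Air 1 and Air 2, and 14.15 M and 14.17 M in EtOH 1 and EtOH 2. Estimates that fall to 0 in single libraries stay open: pairs of 1 Air and 1 EtOH library shared 22 to 44 such transcripts, the Air pair 56, the EtOH pair 12, and the median pair of libraries 3, but for genes the Air pair shared 7 and these mixed pairs only 1, 1, 1 and 3. For the calls of EtOH against Air, grouping Air 1 with EtOH 2 against Air 2 with EtOH 1 gave 98 transcripts, as many as the 97 of the real groups, with 10 genes against 11. Grouping by the letter of the title gave 364 genes and 160 transcripts, which points to a structure of these 4 libraries. With the letter as a block 14 genes and 83 transcripts passed, among them 11 of the 11 genes and 81 of the 97 transcripts. Both letters occur alike in Air and EtOH, so the block leaves the difference between these groups in place. The kept calls therefore cannot decide on that structure as a source. An effect of ethanol remains possible beside values that fall to 0.

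The genes aay, Nmdmc, CG5958 and Cyp4e3 differed between Trained and Odors alongside fat body and hemolymph markers, but in the Air and EtOH libraries aay, Nmdmc and CG5958 lay at levels that overlap those of Trained and not those of Odors, so a change in the Odors flies is as open as one with the pairing. With those markers as a covariate 4 of the 4 genes kept a difference above 2 SE and above 50% of its size, and 4 of the 4 did with muscle markers. The fat body sum was 1911 to 2604 CPM in the Trained libraries and 864 to 1759 in the Odors libraries. Since these ranges do not overlap, the covariate cannot be separated from the comparison, and fat body RNA as the source stays open. None of the 13 listed fat body genes is in another list, its most abundant member apolpp averaged 1078 ± 185 CPM in Trained and 718 ± 165 in Odors (SD, n = 4 each), and the nuclei had been selected by GFP. CG5958 moved most, from a log2 change of 1.13 (SE 0.211) to 0.64 (SE 0.235). A shift in serine, folate and purine metabolism may be involved for aay and Nmdmc, but 22 further genes of these pathways gave a median log2 change of 0.13 with camera p of 0.000484 at the preset correlation and 0.065 with an estimated correlation, which decides neither way.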

How the results depend on the processing

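Alternatives chosen after seeing the data were all 14 columns, the muscle and fat body marker covariates, Odors 1 and 3 left out together, and robust empirical Bayes moderation. Across the alternatives, 150 counts and summary values stayed within 1.5 times of the reported one or kept direction, 125 moved further and 3 reversed. For single genes, lists and usage values, 1717 kept direction and side of the threshold, 124 lost it, 24 gained it, 17 reversed and 6 moved. The cause was not tested for any change below unless stated.

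With DESeq2's Wald test the genes called were 12 for Trained against Odors (edgeR 0), 94 for EtOH against Air (11), 262 for Odors against Air (25), 214 for Trained against EtOH (2), 59 for the interaction (10), 16 for odor order (1) and 14 for odor order by training (1). Transcripts called were 313 (0), 1689 (97), 2225 (123), 1470 (29) and 1455 (77) in the first 5 of these. limma's diffSplice called 98 genes for usage in EtOH against Air (39) and 222 in Odors against Air (53). Every gene and transcript called by edgeR was also called by DESeq2. Without a low-count filter the usage count of Trained against Odors was 2 (5) and odor order gave 2 genes.

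A fit of the compared libraries alone called 0 genes, 0 transcripts and 3 usage genes for EtOH against Air, 14 genes, 191 transcripts and 93 usage genes for Odors against Air, and 5 genes and 157 transcripts for Trained against EtOH. It called 7 transcripts and 15 usage genes for Trained against Odors, 4 genes for odor order and 2 for odor order by training. The values of EtOH against Air then rest on fewer libraries for the spread. Air and EtOH libraries also lay further apart within their groups. On the first principal component Air scored -114 and 82.9 and EtOH -141 and 16.7. Trained scored -7.70 to 71.7 and Odors -54.9 to 51.1. A spread shared by all 12 libraries may therefore be too small for Air and EtOH, and the p-values of EtOH against Air too small as well.

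Replicate numbers did not pair the libraries: deviations of Trained and Odors libraries with the same number correlated at 0.14, -0.076, 0.369 and -0.133, and 2 of 4 Trained libraries were closest to their own number. Air and EtOH libraries of the same letter correlated at 0.476, a value that 2 pairs share. Over all pairs of libraries of different groups, the median was 0.129 with the same letter and -0.0899 with different letters. With the replicate block, Trained against EtOH gave 1 gene, usage counts were 1 for Trained against Odors, 25 for EtOH against Air and 35 for Odors against Air, and odor order and odor order by training gave 0. With the block 6 calls of single genes or usage were lost. With a term for odor order, Odors against Air gave 14 genes, Trained against EtOH 1 and usage in Trained against Odors 0, which was also 0 with the replicate block and odor order together.

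With all 14 columns, every gene and usage count was 0, and transcripts were 0 for EtOH against Air, 2 for Odors against Air, 2 for Trained against EtOH and 0 for the interaction. With the muscle marker covariate, Trained against EtOH gave 1 gene, usage in Trained against Odors 1, odor order 0 and odor order by training 2. With the fat body marker covariate, genes were 10 for Odors against Air, 4 for Trained against EtOH, 2 for odor order and 2 for odor order by training. Transcripts were then 76 for Odors against Air and 50 for the interaction, and usage counts 49 for Trained against Odors and 133 for Odors against Air. With Odors 1 and 3 left out, Odors against Air gave 14 genes and Trained against Odors 2 transcripts. Robust moderation gave 2 genes for odor order. With an estimated correlation in camera, 0 of the 27 list calls over 5 comparisons remained.

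Leaving out 1 library at a time gave 0 genes in every case for Trained against Odors, 37 to 271 for EtOH against Air (271, 55, 40 and 37 without Air 1, Air 2, EtOH 1 and EtOH 2) and 13 to 507 for Odors against Air (507, 71, 15, 13 and 13 without Air 1, Air 2, Odors 1, Odors 2 and Odors 4). Trained against EtOH gave 1 to 57 (23 and 57 without EtOH 1 and EtOH 2, 1 without each Trained library) and the interaction 9 to 251 (251, 40 and 36 without Air 1, Air 2 and EtOH 1). With 1 library left in a group, it is assumed to vary like the other groups. Transcripts were 0 to 3 for Trained against Odors (3 without Odors 4, 2 without Odors 3, Trained 1 or Trained 4, 1 without Trained 2 or Trained 3) and 219 to 668 for EtOH against Air (668, 312, 219 and 306 without Air 1, Air 2, EtOH 1 and EtOH 2). They were 110 to 795 for Odors against Air (795 and 352 without Air 1 and Air 2), 20 to 242 for Trained against EtOH (166 and 242 without EtOH 1 and EtOH 2), and 75 to 618 for the interaction (618, 285, 198 and 246 without Air 1, Air 2, EtOH 1 and EtOH 2). Usage counts were 1 to 8 for Trained against Odors (3, 2, 1 and 2 without Trained 1 to 4, and 8, 2 and 3 without Odors 1, 3 and 4), 14 to 36 for EtOH against Air (14, 18 and 25 without Air 1, Air 2 and EtOH 1) and 37 to 51 for Odors against Air. Odor order gave 0 to 4 genes (0 without Trained 2 or Odors 4, 3, 2 and 4 without Odors 1, Odors 2 and Trained 4). Odor order by training gave 0 to 5 (0 without Trained 1, Trained 2 or Odors 4, 3, 5, 2 and 5 without Odors 1, Odors 2, Trained 3 and Trained 4). The calls of Argk1, pHCl-1, su(r) and Pp2B-14D in Odors against Air, and of tyf in Trained against EtOH, were each lost without at least 1 library.

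Reversals of single genes were of small changes that had not passed. In Trained against Odors, sca was -0.018 and Dop2R -0.037 with Odors 1 and 3 left out; with single libraries out, sca ranged from -0.014 to 0.12 (lowest without Odors 3) and N from -0.41 to 0.019 (highest without Trained 1). In EtOH against Air, Stat92E was -0.017 with the fat body covariate, and Dop2R ranged from -0.42 to 0.21 (highest without Air 2). In Odors against Air, sca was -0.11 with the fat body covariate and ranged from -0.030 to 0.19 (lowest without Air 1), and N ranged from -0.073 to 0.24 (negative without Odors 4, and without Air 1). There Stat92E was -0.028 with RLE scaling, -0.027 with DESeq2, -0.19 with the fat body covariate and -0.047 with Odors 1 and 3 out, and ranged from -0.021 to 0.058 (lowest without Odors 1); Dop2R was 0.065 with Odors 1 and 3 out and ranged from -0.39 to 0.25 (highest without Air 2). The correlation of both ethanol changes across genes was 0.0591 among genes with a mean of at least 100 counts, and ranged from -0.232 to 0.182 with single libraries out (0.182 without EtOH 1, 0.0282 without Odors 3). The changes of Stat92E (0.54 to 0.63), aay (0.98 to 1.18), Nmdmc (1.42 to 1.75), CG5958 (0.999 to 1.24) and Cyp4e3 (-2.29 to -1.72) in Trained against Odors kept direction with any single library out. Depth was not varied. At the fitted spread, 2% of simulated 4-fold changes of transcripts were recovered for Trained against Odors.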

Other observations

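The list of serine, folate and purine genes and the check of main transcripts were chosen only after gene results were seen. For genes and transcripts of Trained against Odors the splits of these libraries decide nothing, because the real counts were 0 and all 35 of the 35 splits reach that for genes (highest other split 1) and all 35 for transcripts (highest other split 6). With edgeR, 221 genes and 744 transcripts had an unadjusted p under 0.05, and DESeq2 called 12 and 313. For transcript usage, chance cannot be excluded: 20 of the 35 splits gave at least the real 5 genes, and the highest other gave 19. For the odor order, the 18 splits are too few for a share under 0.05, with 1 gene in the real split and 1 in the highest other.

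Among the 22 further genes of serine, folate and purine metabolism, 17 were higher and 5 lower in Trained than in Odors. Gart (log2 1.40, SE 0.450) and Shmt (0.77, SE 0.32) had an unadjusted p under 0.05, and both encode enzymes of purine or folate metabolism. Genes first noticed, which were left out of that set, included Gnmt (log2 1.54), Prat2 (1.07), Tdh (0.95) and su(r) (0.85). Gart averaged 85.0 CPM in Air, 54.9 in EtOH, 21.8 in Odors and 57.4 in Trained, and Shmt 185, 159, 88.5 and 151. Odors also had the lowest mean of all groups for Gnmt, Prat2, Tdh and su(r). For these genes a change in the Odors flies is as open as one with the pairing.

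Among 8967 transcripts with a median above 10 CPM, 748 and 926 were at 0 in Air 1 and Air 2, 488 and 618 in EtOH 1 and EtOH 2, and 186 to 435 in the Odors and Trained libraries. The transcripts of Gyf traded places between libraries: Gyf-RG was at 0 in Odors 1 and 2 and at 342 and 343 CPM in Odors 3 and 4, while Gyf-RH was at 353 and 316 CPM in Odors 1 and 2 and at 1.24 and 6.85 in Odors 3 and 4.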
